A study of Mus musculus with 20 samples.

How the data were processed

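Gene expression was measured with one-colour microarrays in microglia, the resident macrophages of the brain, purified by fluorescence-activated cell sorting. Per the labels, the animals were littermates aged 8.5 months of 4 genotypes: WT, mice lacking the lipid-sensing microglial receptor Trem2 (Trem2-/-), 5XFAD mice, which carry human amyloid precursor protein and presenilin transgenes and form amyloid plaques, and 5XFAD mice lacking Trem2 (Trem2-/-5XFAD). Per the labels' protocols, animals were perfused with saline, brains were dissociated with a commercial kit, cells were sorted straight into lysis buffer, RNA was purified on columns, and biotinylated cRNA was made from 2 ng of total RNA. Such small inputs need amplification, which adds noise to weakly expressed genes. The sorting gate and the sex of the animals are not given in the sources used here.

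The table the authors deposited holds linear intensity values for 24679 probe sets on 20 arrays. The tool, the summary method and the normalization that produced it are not given in the sources used here. The column medians lay between 25.7 and 28.6 and the 75th percentiles between 101 and 112, so the arrays had been brought to a common scale, although their quantiles were not identical. No 2 columns were identical. Correlations of log2 values between arrays, over all 24679 probe sets, ran from 0.967 to 0.992. Values ranged from 1.73 to 12110 intensity units.

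The platform annotation used here named 1 gene for 21354 probe sets and several genes for 1275, and 2050 probe sets were not named in it. Of the 21354 probe sets with 1 gene, 21277 matched a gene of the reference table, of the GRCm38.p6 assembly, which served only for names, chromosomes and gene order. Probe sets with several genes were not used to name genes. Where a gene had several probe sets, the one with the highest mean over the assigned arrays stood for it; this concerned 893 of 19751 genes. Among the genes called in 5XFAD vs WT, 132 had several probe sets, and in 2 of them another probe set moved the opposite way at an unadjusted limma p under 0.05; in the other comparisons there were none. Genes of the H2 family share sequence, and their probe sets may report more than 1 member.

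Values were transformed as log2(intensity + 1), with a pseudocount of 1, so folds of weakly expressed genes are understated. A gene was tested if its value exceeded the 40th percentile of the array in at least 4 assigned arrays, which left 12728 genes. No further normalization was applied. The 4 groups held 4 WT, 4 Trem2-/-, 5 5XFAD and 6 Trem2-/-5XFAD arrays. One array carries a title of 1 group (WT) and a genotype and source of another (Trem2-/-); it was put in no group. The number of arrays limits the precision of all values. The labels call the animals littermates but do not say how separate the samples otherwise are, so p-values measure the spread between arrays.

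Differences were tested with limma 3.58.1 in R 4.3.3, in 1 model over the 19 assigned arrays (residual degrees of freedom 15, prior degrees of freedom 5.29), with moderated statistics and Benjamini-Hochberg adjustment over the 12728 genes. The contrasts were 5XFAD vs WT, Trem2-/-5XFAD vs 5XFAD, Trem2-/- vs WT, Trem2-/-5XFAD vs Trem2-/-, and the interaction, which is the change with 5XFAD in Trem2-/- mice minus the change with 5XFAD in mice with Trem2. Genes with an adjusted p under 0.05 are called higher or lower. All adjusted p-values of single genes in the text come from this limma model. Errors beside log2 differences are standard errors. "Adjusted over the list alone" means that the Benjamini-Hochberg step ran over the tested members of a list.

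The lists of genes were fixed before the data were examined: genes raised in disease-associated microglia (DAM), homeostatic microglial genes, type I interferon response, antigen presentation, lysosome, cholesterol synthesis, lipid handling, complement, cytokines and chemokines, growth and repair factors, TREM and TYROBP signalling, phagocytic receptors, cell cycle, glycolysis, oxidative phosphorylation, integrated stress response, apoptosis and survival, immediate early genes, and markers of neurons, astrocytes, oligodendrocytes, vascular cells, monocytes, border macrophages, neutrophils, lymphocytes and erythroid cells. The DAM list comes from a later study of the same mouse model on other samples. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 27 lists within a contrast. Camera with an estimated correlation and limma's fry were alternatives. Camera asks whether a list moved more than other genes, and fry whether it moved at all. Genes named in the text follow a rule fixed before the data were examined: Trem2 first, the 8 largest called increases and 8 largest called decreases of each contrast, the 4 members of each list with the smallest p, and a fixed set of microglial genes, Apoe, Cst7, Itgax, Clec7a, Lpl, Axl, Csf1, Tyrobp, P2ry12, Tmem119 and Cx3cr1 among them, whatever their values. Any other gene named came from a choice made after values were seen.

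The pipeline was tested on simulated data with the real group sizes and per-gene spread, with 200 of 12728 genes changed. In 5XFAD vs WT, log2 changes of 0.5 were recovered in 32%, of 1 in 94%, and of 2 and 3 in 100% of 50 genes each, with 8 false calls among 171. For the interaction the recovered shares were 8%, 64%, 98% and 100%, with 3 false calls among 138.

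Alternatives listed before the data were examined were no low-signal filter or a filter at the 60th percentile, a second quantile normalization, centring arrays on their median, the mean of a gene's probe sets, each placement of the array with conflicting labels, array weights, a trended and robust prior, models of only the groups compared, the replicate number as a block, a covariate of other brain cells' markers, a covariate of Y-linked genes minus Xist, a pseudocount of 16, a minimum change of 1.5 times, and leaving out each array. Others were added later. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.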

Results

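Gene expression was compared in sorted microglia from brains of 8.5-month-old littermates that did or did not carry the 5XFAD transgenes and did or did not have Trem2. The data comprised 4 WT, 4 Trem2-/-, 5 5XFAD and 6 Trem2-/-5XFAD arrays, plus 1 array whose labels conflict and which entered no comparison. Intensities had a median between 25.7 and 28.6 on each of the 20 arrays, and 12728 genes were tested.

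Trem2 was measured first in every array, as it checks the genotype labels. On the log2 scale it averaged 11.31 ± 0.12 in WT (SD, n = 4; range 11.14 to 11.39) and 11.68 ± 0.14 in 5XFAD (SD, n = 5; 11.45 to 11.80). It averaged 6.96 ± 0.08 in Trem2-/- (SD, n = 4; 6.84 to 7.02) and 7.05 ± 0.29 in Trem2-/-5XFAD (SD, n = 6; 6.75 to 7.60). No array of a Trem2-/- group reached the lowest array of a group with Trem2. Where the probe set lies relative to the deleted part of the gene is not given in the sources used here, so the remaining signal is reported only as measured. The array with conflicting labels had a value of 11.08.

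Other measured differences between the groups accompanied genotype. Xist, transcribed from the inactive X chromosome of females, was high (log2 8.61 to 9.52) in 3 of 4 WT, 3 of 4 Trem2-/- and 1 of 5 5XFAD arrays. Signal of Y-linked genes was present in the remaining arrays, which included all 6 of Trem2-/-5XFAD. Genotype and sex signal were therefore partly confounded. The neutrophil marker list averaged 7.08 in Trem2-/- 1 and 7.15 in Trem2-/-5XFAD 1, against 4.77 to 6.52 in the other assigned arrays. Transcripts typical of salivary gland were high in WT 1, WT 2, 5XFAD 1 and 5XFAD 2. Klk1b22, a kallikrein chosen after its values were seen, lay between 7.91 and 9.51 in these 4 arrays and reached at most 3.80 in any other assigned array. Some of these transcripts were also raised in Trem2-/- 3, such as Mucl2, chosen in the same way, at 9.65.

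The comparison of 5XFAD with WT asked how microglia change in a brain with amyloid plaques. Gpnmb, a lysosomal and cell-surface glycoprotein, rose by 5.54 ± 0.26 on the log2 scale (46.5 times; limma, adjusted p = 5.6e-12). Its WT mean of 3.85 lay under the 40th percentile of the arrays (16.9 to 19.2 intensity units), so this fold is a lower limit. The same holds for Mamdc2 and Hpse below (WT means 3.52 and 3.69). Fabp5, a fatty acid-binding protein, rose by 5.01 ± 0.26, the protease inhibitor Cst7 by 4.81 ± 0.17, Mamdc2 by 4.64 ± 0.23 and lipoprotein lipase (Lpl) by 4.47 ± 0.18, each with 4 WT and 5 5XFAD arrays. Gpr165 fell by 2.12 ± 0.26, the B-cell scaffold gene Bank1 by 2.02 ± 0.18, the lectin receptor Clec4a2 by 1.99 ± 0.17 and Serpinf1, which encodes a secreted neurotrophic factor, by 1.98 ± 0.11. In all, 1047 genes were higher and 862 lower in 5XFAD, 15.0% of those tested, with a median standard error of 0.146. After a second quantile normalization it was 961 higher and 1074 lower, so which direction held more genes depended on the scaling.

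Of 43 tested genes of the DAM list, which comes from a later study of the same mouse model on other samples, 37 rose in 5XFAD and the other 6 did not pass the test. The count was 40 adjusted over the list alone, and the median log2 difference was 1.55 (camera adjusted p = 6.8e-56). Itgax, an integrin subunit, rose by 4.19 ± 0.17, the heparan sulfate-cleaving enzyme Hpse by 4.35 ± 0.18, the phagocytic receptor kinase Axl by 3.51 ± 0.18 and the lipid carrier Apoe by 1.55 ± 0.14. Of 33 homeostatic genes 28 fell, 29 adjusted over the list alone, with a median of -0.58 (adjusted p = 5.2e-27). Among them the purinergic receptor P2ry12 fell by 0.80 ± 0.11, the microglial membrane protein Tmem119 by 0.96 ± 0.09 and the fractalkine receptor Cx3cr1 by 0.50 ± 0.08. The differences of Trem2 (0.36 ± 0.13, limma adjusted p = 0.0731) and of its adaptor Tyrobp (0.23 ± 0.08, adjusted p = 0.0652) did not pass the test.

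Further lists rose in 5XFAD. Of 34 type I interferon genes 20 rose, 24 adjusted over the list alone, including Oasl2 by 2.17 ± 0.23 and the antiviral membrane protein Ifitm3 by 1.66 ± 0.19 (list median 0.73, camera adjusted p = 1.3e-12). Of 21 antigen presentation genes 8 rose and 1 fell, with 9 and 1 adjusted over the list alone (median 0.29, adjusted p = 3.6e-06). The MHC class II invariant chain Cd74 rose by 1.77 ± 0.18. Of 23 cholesterol synthesis genes 11 rose, 15 adjusted over the list alone, including the regulator Srebf2 by 1.13 ± 0.12 and the sterol demethylase Cyp51 by 1.53 ± 0.18 (median 0.55, adjusted p = 2.3e-08). Lipid handling had 14 genes higher and 2 lower of 34, and 14 and 3 adjusted over the list alone, with the lipid-droplet protein Plin2 up by 1.79 ± 0.14 (median 0.25, adjusted p = 2.1e-06). Growth and repair factors had 13 of 24 higher, 17 adjusted over the list alone, among them Igf1 by 4.31 ± 0.27 and the angiogenic factor Vegfa by 1.52 ± 0.18 (median 0.53, adjusted p = 1.8e-09). Cytokines and chemokines had 13 higher and 5 lower of 34, and 16 and 5 adjusted over the list alone, with Ccl6 up by 1.61 ± 0.10 and Il12b by 2.45 ± 0.18 (median 0.54, adjusted p = 1.3e-06). Glycolysis had 11 higher and 2 lower of 24, and 12 and 3 adjusted over the list alone, with the enzyme Tpi1 up by 1.34 ± 0.12 and the glucose transporter Slc2a1 by 1.48 ± 0.13 (median 0.47, adjusted p = 7.0e-06). These 9 lists, DAM and homeostatic genes included, were also called with an estimated correlation, at larger camera adjusted p-values. These were 4.5e-06 for DAM, 7.0e-04 for homeostatic genes, 5.7e-05 for growth factors and 0.00283 for cholesterol synthesis. They were 0.0247 for type I interferon, antigen presentation, lipid handling and glycolysis, and 0.0381 for cytokines.

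The remaining lists that camera called in 5XFAD vs WT lost the call with an estimated correlation, while fry called each of them. Lysosomal genes had 16 higher and 2 lower of 44, 18 and 2 adjusted over the list alone, with the galactosidase Glb1 up by 1.08 ± 0.12 (median 0.26, camera adjusted p = 2.5e-07; adjusted p = 0.200 with an estimated correlation). Oxidative phosphorylation had 12 of 38 higher, 16 adjusted over the list alone (median 0.23, adjusted p = 2.1e-06; adjusted p = 0.224 with an estimated correlation). Cell cycle genes had 2 of 32 higher, 1 adjusted over the list alone (median 0.25, adjusted p = 0.00515; adjusted p = 0.163 with an estimated correlation). Immediate early genes had 4 higher and 9 lower of 29, 4 and 14 adjusted over the list alone (median -0.25, adjusted p = 0.0155; adjusted p = 0.408 with an estimated correlation). Here the orphan nuclear receptor Nr4a3 rose by 1.80 ± 0.18 and the transcription factor Klf2 fell by 1.01 ± 0.12.

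Markers of other cells moved beside these groups. Of 16 border macrophage markers, typical of perivascular and meningeal macrophages, 6 fell in 5XFAD, 8 adjusted over the list alone, including the transcription factor Maf by 1.10 ± 0.13 and the scavenger receptor Stab1 by 0.98 ± 0.15 (list median -0.69, camera adjusted p = 3.1e-04; adjusted p = 0.245 with an estimated correlation). Monocyte markers had 3 of 10 higher, and 3 higher and 1 lower adjusted over the list alone, with Anxa2 up by 2.77 ± 0.18 (median 0.17, adjusted p = 0.0165; adjusted p = 0.277 with an estimated correlation). The astrocyte intermediate filament gene Gfap rose by 2.16 ± 0.18, while the astrocyte list (2 of 13 higher, 2 lower; median 0.19, adjusted p = 0.227) was not called by camera. The lists that did not pass camera's test, of which fry called complement, TREM and TYROBP signalling, phagocytic receptors and oligodendrocytes as well as astrocytes, were complement (median 0.05, adjusted p = 0.270), TREM and TYROBP signalling (-0.18, 0.152), phagocytic receptors (-0.02, 0.187), integrated stress response (0.02, 0.496), apoptosis and survival (0.08, 0.988), and markers of neurons (0.13, 0.253), oligodendrocytes (0.05, 0.469), vascular cells (0.01, 0.988), neutrophils (0.01, 0.984), lymphocytes (-0.04, 0.514) and erythroid cells (0.01, 0.984). A covariate of the markers of neurons, astrocytes, oligodendrocytes and vascular cells did not overlap between WT (5.24 to 5.37) and 5XFAD (5.41 to 5.50). It therefore also takes out part of the genotype difference, and its lists hold Gfap and Flt1, up by 2.16 and 2.95. With this covariate the number of called genes was 926. It was 856 among arrays with Y-linked signal alone, where WT had 1 array, and 444 among arrays with Xist signal alone, where 5XFAD had 1 array; these subsets were chosen after seeing the data.

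**Figure D1:**
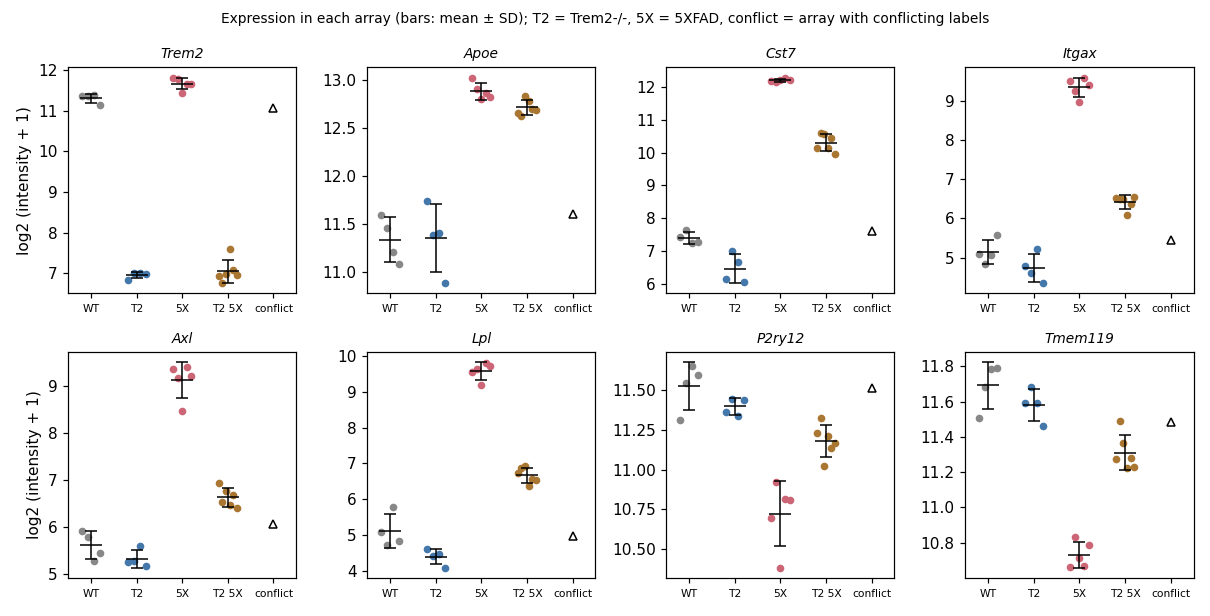
Log2 intensity of 8 genes in each array, with one point per array and bars giving the mean ± SD of each genotype (n = 4, 4, 5 and 6); the triangle is the array with conflicting labels. Cst7 averaged 12.21 in 5XFAD, 10.31 in Trem2-/-5XFAD and 7.40 in WT, and Apoe averaged 12.89, 12.72 and 11.34 in the same groups.

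The comparison of Trem2-/-5XFAD with 5XFAD asked how microglia of the Trem2 genotypes differ in the brain with plaques. Besides Trem2 itself, which fell by 4.63 ± 0.12, the X-linked transcript G530011O06Rik fell by 4.74 ± 0.25, Mamdc2 by 4.29 ± 0.21, the transcription factor Bhlhe40 by 3.75 ± 0.24, Atp6v0d2, a subunit of the lysosomal proton pump, by 3.37 ± 0.17, and Gpnmb by 3.03 ± 0.24 (limma, adjusted p = 2.0e-08; 5 and 6 arrays). Rasgrf2, an exchange factor for Ras, rose by 2.91 ± 0.21, the natural killer receptor subunit Klrd1 by 1.59 ± 0.39, the phospholipase Pla2g7 by 1.53 ± 0.24 and Gpr165 by 1.32 ± 0.24. In all, 409 genes were higher and 568 lower in Trem2-/-5XFAD, with a median standard error of 0.132. With each array centred on its median the split was 286 higher and 625 lower, and after a second quantile normalization 523 higher and 499 lower, so the excess of lower genes depended on the scaling.

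Of the 43 DAM genes 26 fell, 31 adjusted over the list alone, with a median of -0.79 (camera adjusted p = 2.3e-47). Itgax fell by 2.92 ± 0.15, Lpl by 2.91 ± 0.16, Axl by 2.49 ± 0.16 and Cst7 by 1.90 ± 0.15. Apoe did not pass the test (-0.17 ± 0.12, limma adjusted p = 0.481). Of 33 homeostatic genes 18 rose, 25 adjusted over the list alone (median 0.32, camera adjusted p = 8.9e-18), with Tmem119 up by 0.58 ± 0.08, P2ry12 by 0.46 ± 0.10 and Cx3cr1 by 0.33 ± 0.07. Of 23 cholesterol synthesis genes 12 fell, 14 adjusted over the list alone, Srebf2 by 1.12 ± 0.11 and Cyp51 by 1.49 ± 0.16 (median -0.49, adjusted p = 4.7e-12). Of 21 antigen presentation genes 9 fell, 10 adjusted over the list alone (median -0.29, adjusted p = 5.5e-10). Cd74 fell by 2.15 ± 0.16 and the MHC class II chain H2-Aa by 2.27 ± 0.25. Growth and repair factors had 10 lower and 1 higher of 24, and 11 and 1 adjusted over the list alone, with Igf1 down by 2.36 ± 0.24 and Vegfa by 1.49 ± 0.16 (median -0.29, adjusted p = 1.8e-07). Glycolysis had 10 lower and 1 higher of 24, and 11 and 1 adjusted over the list alone, with Slc2a1 down by 0.92 ± 0.12 (median -0.32, adjusted p = 1.2e-06). These 6 lists were also called with an estimated correlation, at larger camera adjusted p-values. These were 1.3e-05 for DAM, 0.00318 for homeostatic genes and antigen presentation, 5.1e-04 for cholesterol synthesis, 2.9e-04 for growth factors and 0.0189 for glycolysis.

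Another 10 lists called by camera in this comparison lost the call with an estimated correlation, while fry called all of them but immediate early genes (fry adjusted p = 0.0558). Of 16 border macrophage markers 11 rose, 12 adjusted over the list alone (median 0.89, camera adjusted p = 2.3e-09; adjusted p = 0.0631 with an estimated correlation). They included the mannose receptor Mrc1 by 1.28 ± 0.28, the haemoglobin scavenger receptor Cd163 by 0.88 ± 0.20 and Stab1 by 0.91 ± 0.13. Neutrophil markers had a median of 0.62 with none of 10 members called, and 1 called adjusted over the list alone (adjusted p = 0.0155; adjusted p = 0.291 with an estimated correlation). Oxidative phosphorylation had 8 of 38 lower, 14 adjusted over the list alone (median -0.24, adjusted p = 4.7e-10; adjusted p = 0.107 with an estimated correlation). Cytokines and chemokines had 9 lower and 3 higher of 34, 11 and 4 adjusted over the list alone (median -0.25, adjusted p = 7.5e-05; adjusted p = 0.107 with an estimated correlation). Type I interferon genes had 8 of 34 lower, 9 adjusted over the list alone, with Slfn5 down by 1.02 ± 0.18 (median -0.25, adjusted p = 7.5e-05; adjusted p = 0.236 with an estimated correlation). Lysosomal genes had 5 of 44 lower, and 7 lower and 1 higher adjusted over the list alone (median -0.06, adjusted p = 4.2e-04; adjusted p = 0.343 with an estimated correlation). TREM and TYROBP signalling had 6 higher and 3 lower of 28, 8 and 3 adjusted over the list alone, with the inhibitory receptor Cd33 up by 0.59 ± 0.10 (median 0.15, adjusted p = 0.0347; adjusted p = 0.265 with an estimated correlation). Lipid handling had 7 lower and 5 higher of 34, 8 and 7 adjusted over the list alone (median -0.04, adjusted p = 0.0391; adjusted p = 0.291 with an estimated correlation). Phagocytic receptors had 6 lower and 3 higher of 34, 8 and 4 adjusted over the list alone (median -0.02, adjusted p = 0.0391; adjusted p = 0.291 with an estimated correlation). Immediate early genes had 4 higher and 3 lower of 29, 5 and 3 adjusted over the list alone, with Klf2 up by 0.67 ± 0.11 (median 0.15, adjusted p = 0.0298; adjusted p = 0.433 with an estimated correlation).

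The lists camera did not call in Trem2-/-5XFAD vs 5XFAD, of which fry called complement, neurons and astrocytes, were complement (median 0.01, camera adjusted p = 0.313), cell cycle (-0.05, 0.170), integrated stress response (0.06, 0.943), apoptosis and survival (0.12, 0.388), and markers of neurons (-0.21, 0.0671), astrocytes (-0.08, 0.0842), oligodendrocytes (-0.01, 0.667), vascular cells (0.15, 0.472), monocytes (0.09, 0.261), lymphocytes (0.16, 0.130) and erythroid cells (-0.03, 0.654). Gfap fell by 0.76 ± 0.16. The number of called genes was 459 with the covariate of other brain cells and 579 without WT 1, WT 2, 5XFAD 1 and 5XFAD 2, a choice made after seeing the data.

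**Figure D2:**
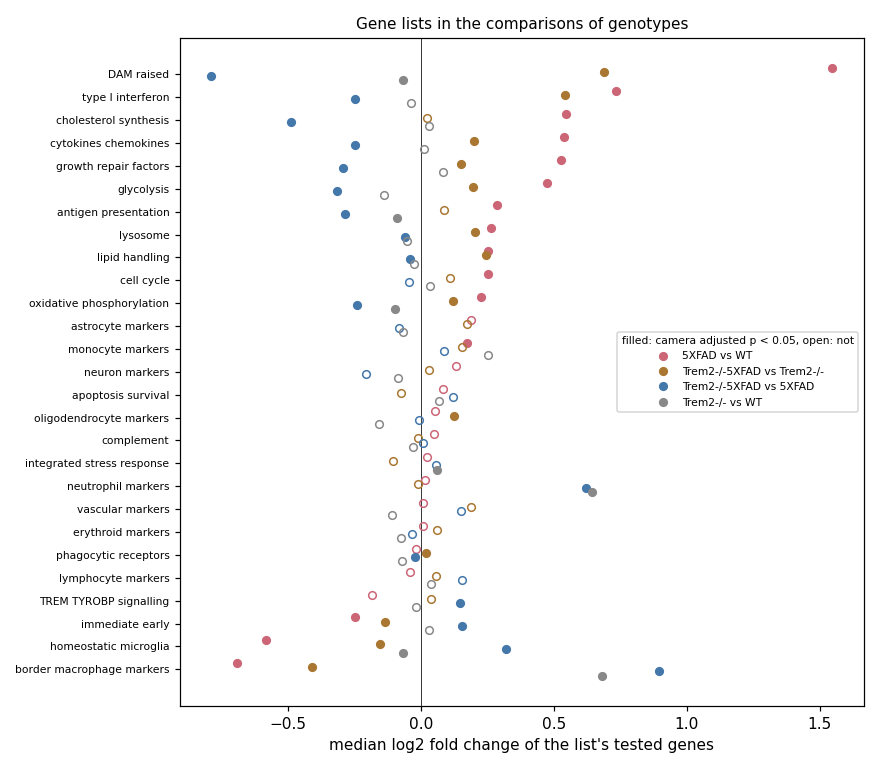
Median log2 fold change of each gene list (horizontal axis) in 4 comparisons of genotypes, with filled points where camera gave an adjusted p under 0.05 at the preset correlation and open points elsewhere. The DAM list lay at 1.55 in 5XFAD vs WT, 0.69 in Trem2-/-5XFAD vs Trem2-/- and -0.79 in Trem2-/-5XFAD vs 5XFAD, and the border macrophage markers at -0.69, -0.41 and 0.89.

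The comparison of Trem2-/- with WT asked how microglia of the Trem2 genotypes differ without plaques. It gave the fewest called genes of the 5 contrasts, 49 higher and 29 lower, with a median standard error of 0.154. The excess of higher genes depended on the settings: it was 10 higher and 16 lower with the conflicting array in WT, 5 and 6 in a model of these groups alone, 10 and 14 with the covariate of other brain cells, 7 and 14 with that of neutrophil markers, and 7 and 38 among arrays with Y-linked signal. Trem2 fell by 4.36 ± 0.14, G530011O06Rik by 6.85 ± 0.29, the X-linked ubiquitin ligase gene Mid1 fell by 3.31 ± 0.22, Lrmda by 2.39 ± 0.35 and Enpp5 by 1.94 ± 0.18. Rasgrf2 rose by 2.53 ± 0.25, the clock repressor Nr1d1 by 1.51 ± 0.27, the transcriptional repressor Bcl6 by 1.49 ± 0.33 and Gch1, an enzyme of tetrahydrobiopterin synthesis, by 1.49 ± 0.29 (limma, adjusted p = 0.0183; 4 and 4 arrays). Bcl6 was 9.30 and 9.05 in WT 1 and WT 2 but 7.28 and 7.27 in WT 3 and WT 4, against 9.55 to 9.95 in Trem2-/-. G530011O06Rik, Mid1, Lrmda, Enpp5 and Rasgrf2 also changed alike with Trem2 genotype in mice with 5XFAD. For them, effects of Trem2 were not separated from those of DNA beside it or of other strain differences. The macrophage growth factor Csf1 fell by 0.94 ± 0.14 and Cst7 by 0.94 ± 0.18. Apoe (0.02 ± 0.14), P2ry12 (-0.13 ± 0.11), Tmem119 (-0.11 ± 0.10) and Lpl (-0.71 ± 0.19, adjusted p = 0.115) did not pass the test.

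At the preset correlation 7 lists were called in Trem2-/- vs WT. With an estimated correlation camera called 0 of the 27 lists, and 2 had an unadjusted p under 0.05. Fry called none of the 7, and of the others it called oligodendrocyte markers (fry adjusted p = 0.0129). The number called at the preset correlation was 3 without WT 3 and 4 without Trem2-/- 1. Of 16 border macrophage markers 1 rose, Cd163 by 1.17 ± 0.24, and 6 adjusted over the list alone (median 0.68, camera adjusted p = 6.2e-07; adjusted p = 0.397 with an estimated correlation). Among arrays with Y-linked signal alone, chosen after seeing the data and with 1 array in each group, the direction turned (list median -0.34, Cd163 -0.13). Neutrophil markers had a median of 0.64, with none of 10 called and 1 called adjusted over the list alone (adjusted p = 0.00768; adjusted p = 0.458 with an estimated correlation). S100a8, a neutrophil calcium-binding protein, differed by 2.93 ± 0.89 (limma adjusted p = 0.156). The DAM list had 2 of 43 lower, 5 adjusted over the list alone (median -0.07, adjusted p = 0.00398; adjusted p = 0.458 with an estimated correlation). Antigen presentation had 1 of 21 lower, 1 adjusted over the list alone, the class I gene H2-M3 by -0.84 ± 0.18 (median -0.09, adjusted p = 0.0306; adjusted p = 0.458 with an estimated correlation). Homeostatic genes (median -0.07), oxidative phosphorylation (-0.10) and the integrated stress response (0.06) each had an adjusted p of 0.0306, which was 0.655 with an estimated correlation. None of their members passed over all genes, and 2 stress genes were higher adjusted over the list alone.

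The other lists of Trem2-/- vs WT were not called. Their medians and camera adjusted p-values were -0.04 and 0.971 for type I interferon, -0.05 and 0.175 for lysosome, 0.03 and 0.781 for cholesterol synthesis, -0.03 and 0.971 for lipid handling, -0.03 and 0.971 for complement, 0.01 and 0.943 for cytokines, 0.08 and 0.851 for growth factors, -0.02 and 0.893 for TREM and TYROBP signalling, and -0.07 and 0.222 for phagocytic receptors. They were 0.03 and 0.318 for cell cycle, -0.14 and 0.226 for glycolysis, 0.07 and 0.318 for apoptosis, 0.03 and 0.0536 for immediate early genes, -0.09 and 0.488 for neurons, -0.07 and 0.186 for astrocytes, -0.16 and 0.0653 for oligodendrocytes, -0.11 and 0.947 for vascular cells, 0.25 and 0.107 for monocytes, 0.04 and 0.851 for lymphocytes and -0.08 and 0.606 for erythroid cells. The count of called genes depended on single arrays and choices: it was 159 without WT 2, 42 without WT 3, 30 without Trem2-/- 1, 43 without either Trem2-/- 2 or Trem2-/- 3, and 46 without Trem2-/- 4. It was 26 with the conflicting array placed in WT, 48 with array weights, 11 in a model of these groups alone, 24 with the covariate of other brain cells and 21 with a covariate of neutrophil markers. It was 271 without WT 1, WT 2, 5XFAD 1 and 5XFAD 2, 45 among arrays with Y-linked signal and 10 among arrays with Xist signal; these subsets and the neutrophil covariate were chosen after seeing the data.

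The effect of 5XFAD in mice without Trem2 was then compared with that in mice with Trem2. In Trem2-/-5XFAD vs Trem2-/-, Cst7 rose by 3.84 ± 0.16, the apolipoprotein Apoc1 by 3.67 ± 0.33, Gpnmb by 2.47 ± 0.25, Hpse by 2.31 ± 0.18, Lpl by 2.26 ± 0.18, the beta-glucan receptor Clec7a by 2.18 ± 0.17 and Apoe by 1.36 ± 0.13 (limma, adjusted p = 1.5e-06; 4 and 6 arrays). Sult1a1 fell by 1.27 ± 0.18, Gpr165 by 1.26 ± 0.25 and Serpinf1 by 0.99 ± 0.11. The values of P2ry12 (-0.22 ± 0.10), Tmem119 (-0.27 ± 0.09) and Cx3cr1 (-0.08 ± 0.08) did not pass the test. In all, 207 genes were higher and 71 lower, with a median standard error of 0.140. Centring arrays on their median gave 141 higher and 92 lower.

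In this background 26 of 43 DAM genes rose, 33 adjusted over the list alone (median 0.69, camera adjusted p = 1.2e-52), and 4 of 33 homeostatic genes fell, 11 adjusted over the list alone (median -0.15, adjusted p = 1.6e-11). Type I interferon genes had 8 of 34 higher, and 21 higher and 1 lower adjusted over the list alone (median 0.54, adjusted p = 7.1e-12), with Ifitm3 up by 1.12 ± 0.18 and the chemokine Cxcl10 by 1.35 ± 0.22. Lipid handling had 9 higher and 1 lower of 34, 13 and 1 adjusted over the list alone (median 0.24, adjusted p = 2.6e-09). Growth and repair factors had 5 of 24 higher, 6 adjusted over the list alone, with the matrix protease Mmp12 up by 1.95 ± 0.17 (median 0.15, adjusted p = 7.9e-04). Oligodendrocyte markers had 1 of 11 higher, 4 adjusted over the list alone, the myelin gene Mbp by 0.93 ± 0.12 (median 0.12, adjusted p = 0.00856). These 6 lists were also called with an estimated correlation. Gfap rose by 1.15 ± 0.18 beside them.

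A further 7 lists were called by camera at the preset but not at an estimated correlation, and fry called lysosome, glycolysis, cytokines and phagocytic receptors among them. Lysosome had 8 of 44 higher, 15 adjusted over the list alone (median 0.20, camera adjusted p = 7.5e-09; adjusted p = 0.175 with an estimated correlation), and glycolysis 5 of 24 higher, with 9 higher and 1 lower adjusted over the list alone (0.20, 4.2e-04; adjusted p = 0.0873 with an estimated correlation). Cytokines had 5 of 34 higher, 8 adjusted over the list alone (0.20, 0.00127; adjusted p = 0.175 with an estimated correlation), and phagocytic receptors 5 of 34 higher, with 6 higher and 1 lower adjusted over the list alone (0.02, 0.0233; adjusted p = 0.256 with an estimated correlation). Oxidative phosphorylation had 1 of 38 higher, 2 adjusted over the list alone (0.12, 0.00730; adjusted p = 0.558 with an estimated correlation). Immediate early genes had none of 29 called (-0.13, 1.3e-04; adjusted p = 0.213 with an estimated correlation). Border macrophage markers had 2 of 16 lower, 4 adjusted over the list alone, with Lyve1 down by 1.30 ± 0.34 and Cd163 by 0.90 ± 0.22 (-0.41, 2.4e-05; adjusted p = 0.175 with an estimated correlation). Lists camera did not call, of which fry called astrocytes, were antigen presentation (0.09, 0.211), cholesterol synthesis (0.02, 0.935), complement (-0.01, 0.362), TREM and TYROBP signalling (0.04, 0.8291), cell cycle (0.11, 0.231), integrated stress response (-0.10, 0.216), apoptosis (-0.07, 0.8291), neurons (0.03, 0.662), astrocytes (0.17, 0.0673), vascular cells (0.19, 0.8291), monocytes (0.15, 0.188), neutrophils (-0.01, 0.8291), lymphocytes (0.06, 0.8291) and erythroid cells (0.06, 0.8291). The number of called genes was 86 with the covariate of other brain cells, 159 with a covariate of Y-linked genes minus Xist, 507 with array weights, 158 without Trem2-/- 3, 164 without Trem2-/- 1 and 185 without Trem2-/-5XFAD 4. Among arrays with Y-linked signal alone, chosen after seeing the data, it was 123 with 1 Trem2-/- array, and Lyve1 then differed by 0.22.

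The interaction tested whether the change with 5XFAD differed between the Trem2 genotypes. Large values were found for Mamdc2 (-4.23 ± 0.32), Bhlhe40 (-3.57 ± 0.37), Atp6v0d2 (-3.50 ± 0.25), Egln3, an oxygen-sensing hydroxylase (-3.19 ± 0.44), Fabp5 (-3.09 ± 0.37) and Gpnmb (-3.07 ± 0.36; limma, adjusted p = 3.3e-05; 19 arrays). Mamdc2, Atp6v0d2 and Egln3 lay near the background outside 5XFAD (WT means of 3.52, 3.19 and 3.56), so the sizes of such interactions and their order are approximate. It was smaller for Cst7 (-0.97 ± 0.23), and it was positive for the ribonuclease Rnase12 (2.07 ± 0.42), Bank1 (1.37 ± 0.25), Tmem119 (0.69 ± 0.13) and P2ry12 (0.58 ± 0.15). The interaction of Apoe (-0.19 ± 0.19, adjusted p = 0.733), Csf1 (-0.65 ± 0.18, adjusted p = 0.0614) and Cx3cr1 (0.42 ± 0.11, adjusted p = 0.0526) did not pass the test. In all, 130 genes had a positive and 201 a negative interaction, and 78 and 224 with arrays centred on their median.

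Of the lists, DAM (20 of 43 negative, 23 adjusted over the list alone; median -0.66, camera adjusted p = 2.4e-30), homeostatic genes (11 of 33 positive, 21 adjusted over the list alone; 0.38, 8.6e-19), cholesterol synthesis (9 of 23 negative, 11 adjusted over the list alone; -0.57, 6.0e-10) and growth factors (3 of 24 negative, and 11 negative and 1 positive adjusted over the list alone; -0.25, 2.5e-06) were called with either correlation and by fry, which also called antigen presentation, cytokines and glycolysis but not the other 4 lists below. Srebf2 had an interaction of -1.15 ± 0.17 and Igf1 of -2.23 ± 0.38. Antigen presentation had 4 of 21 negative, and 6 negative and 1 positive adjusted over the list alone, with Cd74 at -1.98 ± 0.25 (-0.27, 1.7e-04; adjusted p = 0.0680 with an estimated correlation). Cytokines had 5 of 34 negative, and 11 negative and 3 positive adjusted over the list alone (-0.32, 1.7e-04; adjusted p = 0.154 with an estimated correlation). Glycolysis had 4 negative and 1 positive of 24, 8 and 2 adjusted over the list alone (-0.23, 0.00207; adjusted p = 0.154 with an estimated correlation). Lipid handling had 7 negative and 2 positive of 34, 8 and 3 adjusted over the list alone (-0.03, 0.0444; adjusted p = 0.395 with an estimated correlation). Monocyte markers had 2 of 10 negative, 2 adjusted over the list alone (-0.15, 0.0390; adjusted p = 0.395 with an estimated correlation). Type I interferon (-0.27, 0.00135; adjusted p = 0.395 with an estimated correlation) and oxidative phosphorylation (-0.16, 0.00207; adjusted p = 0.480 with an estimated correlation) had no called member. Among arrays with Y-linked signal alone, chosen after seeing the data and with 1 array each of WT and Trem2-/-, the cytokine and oxidative phosphorylation lists turned direction.

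The interaction was not called by camera, although fry called oligodendrocytes, for lysosome (median -0.00, camera adjusted p = 0.108), complement (0.07, 0.299), TREM and TYROBP signalling (0.15, 0.0769), phagocytic receptors (0.07, 0.299), cell cycle (-0.08, 0.0769), integrated stress response (-0.13, 0.0769), apoptosis (0.02, 0.871), immediate early genes (0.09, 0.871), neurons (-0.07, 0.479), astrocytes (0.10, 0.871), oligodendrocytes (0.17, 0.299), vascular cells (0.15, 0.913), border macrophages (0.22, 0.351), neutrophils (0.04, 0.871), lymphocytes (0.18, 0.395) and erythroid cells (0.04, 0.871). Median, mean and test differed in sign for 2 lists in 5XFAD vs WT, 4 in Trem2-/-5XFAD vs 5XFAD, 5 in Trem2-/- vs WT, 4 in Trem2-/-5XFAD vs Trem2-/- and 7 in the interaction, none of them called by camera. Among them, fry called phagocytic receptors in 5XFAD vs WT (median -0.02, mean 0.34) and complement in Trem2-/-5XFAD vs 5XFAD (median 0.01, mean -0.15).

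The genes called in 5XFAD vs WT were followed as sets in the Trem2-/- background, where no array is shared. The 1047 raised genes had a median of 0.70 in 5XFAD vs WT and of 0.23 ± 0.04 (SD over 6 Trem2-/-5XFAD arrays) in Trem2-/-5XFAD vs Trem2-/-, where 85.3% kept their sign. Of the 207 genes raised in the latter, 165 were shared, against 17.0 for independent lists. The 862 lowered genes had medians of -0.59 and -0.18 ± 0.03, 81.0% kept their sign, and 44 of 71 were shared, against 4.81. Genes chosen on WT 1 and 2 and 5XFAD 1 to 3 had medians of 0.81 (970 raised genes) and -0.70 (650 lowered genes) in those arrays. In the other arrays of the same genotypes the medians were 0.47 and -0.47, and in the Trem2-/- background 0.22 and -0.18. WT 1, WT 2, 5XFAD 1 and 5XFAD 2, with the gland transcripts, were all among the arrays used for choosing. Of the other arrays, WT 3 and WT 4 had Xist signal and 5XFAD 4 and 5XFAD 5 had Y-linked signal. The medians of 0.47 and -0.47 therefore hold genotype and sex signal together. So do the medians of 0.22 and -0.18, as Xist signal was present in 3 of 4 Trem2-/- and 0 of 6 Trem2-/-5XFAD arrays. An interaction towards a smaller change was called for 198 raised and 122 lowered genes, against a mean of 0.05 and at most 1 raised gene, and 0 lowered genes, in 20 simulations without an interaction. The simulations drew independent noise for each gene, so they leave out variation that genes share and may understate such calls. An interaction towards a larger change was called by limma for 0 raised and 0 lowered genes, and 5 and 0 had one at an unadjusted p under 0.05. Across genes, which are not independent replicates, the changes in the backgrounds correlated with r = 0.573. Other settings chose the raised and lowered genes anew, so their sets differ from the 1047 and 862 genes. In the Trem2-/- background the median of genes raised in that way was 0.41 with the covariate of other brain cells. It was 0.41 among arrays with Y-linked signal, and that of the lowered genes was -0.29 with that covariate. The medians of these sets in 5XFAD vs WT are not given here, so these values do not show a smaller gap between the backgrounds.

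**Figure D3:**
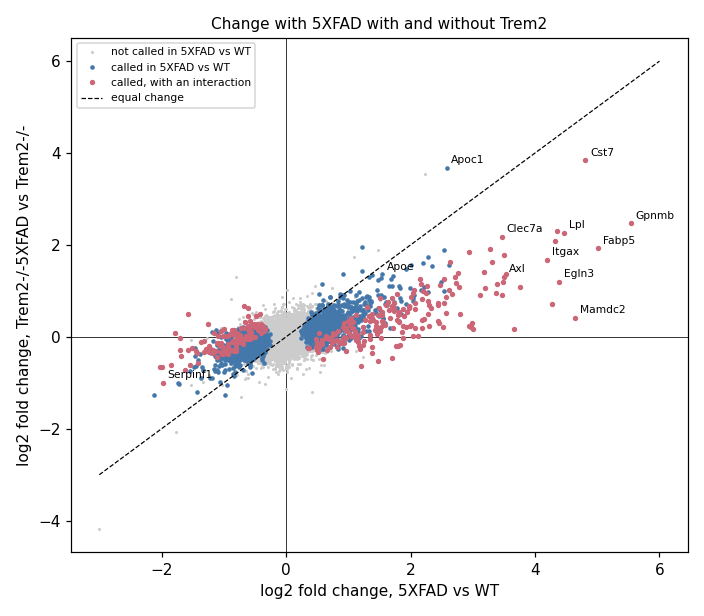
Log2 fold change with 5XFAD of 12728 genes in mice with Trem2 (horizontal axis) and without it (vertical axis), with genes called in 5XFAD vs WT in blue and those that also had an interaction in red; the dashed line marks equal change. Gpnmb lay at 5.54 and 2.47, Lpl at 4.47 and 2.26, and Apoe at 1.55 and 1.36.

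The effect of Trem2 genotype was also compared between animals with and without 5XFAD, which share no array. It was called in the same direction in both for 17 higher genes, against 1.57 for independent lists, and for 14 lower genes including Trem2, against 1.29. G530011O06Rik lay between 3.54 and 6.41 in the 10 arrays of Trem2-/- groups and between 10.08 and 11.37 in the 9 arrays of groups with Trem2. Rasgrf2 lay between 6.20 and 8.07 in the former and between 3.82 and 5.58 in the latter.

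**Figure D4:**
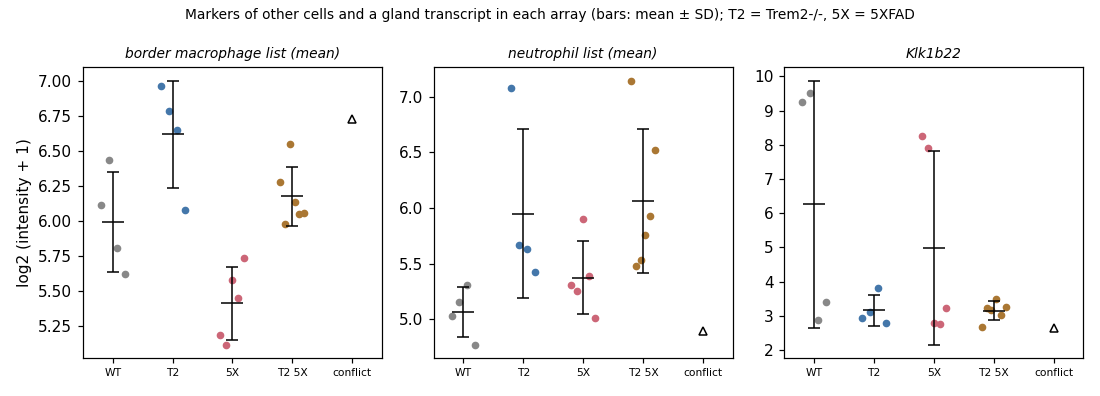
Mean log2 intensity of the border macrophage and neutrophil lists, and log2 intensity of Klk1b22, in each array, with one point per array and bars giving the mean ± SD of each genotype; the triangle is the array with conflicting labels. The border macrophage mean was 5.41 ± 0.26 in 5XFAD (SD, n = 5) and 6.18 ± 0.21 in Trem2-/-5XFAD (SD, n = 6), and Klk1b22 reached 9.51 in WT 2.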

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

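The tests of border macrophages, of DNA beside Trem2 and of salivary gland RNA were chosen only after the results were seen, while the splits of the arrays were planned. Splits of the same arrays into groups of the same sizes were compared with the real split for all 5 counts of called genes. The real split alone reached its count each time: 1909 genes in 5XFAD vs WT against at most 922 in the other splits (1 of 100), 977 in Trem2-/-5XFAD vs 5XFAD against 344 (1 of 100), and 78 in Trem2-/- vs WT against 7 (1 of 35). It was 278 in Trem2-/-5XFAD vs Trem2-/- against 1 (1 of 100) and 331 for the interaction against 2 (1 of 100). These are the lowest shares that so many splits can give, so chance is not excluded. Splits that mix genotypes also have a wider spread within groups, which lowers their counts. For the interaction the splits exchanged Trem2 genotypes within arrays with and without 5XFAD. They therefore bear on any effect of Trem2 genotype, not on the interaction alone. Sex signal is not separated from genotype by the splits.

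The change with 5XFAD differed by Trem2 genotype, by limma's test of the interaction, for genes whose rise was smaller without Trem2. The log2 interaction was -4.23 for Mamdc2, -3.57 for Bhlhe40, -3.50 for Atp6v0d2, -3.19 for Egln3, -3.09 for Fabp5, -3.07 for Gpnmb, -2.84 for Cybb, -2.76 for Dkk2, -2.71 for Flt1, -2.51 for Itgax, -2.23 for Igf1, -2.20 for Lpl, -2.20 for Axl, -2.17 for H2-Aa, -1.98 for Cd74, -1.55 for Cyp51, -1.30 for Clec7a, -1.15 for Srebf2 and -0.97 for Cst7. It was 2.12 for G530011O06Rik, 2.07 for Rnase12, 1.37 for Bank1, 0.69 for Tmem119 and 0.58 for P2ry12. Among gene lists the median interaction was -0.66 for DAM, 0.38 for homeostatic genes, -0.57 for cholesterol synthesis, -0.32 for cytokines, -0.27 for type I interferon, -0.27 for antigen presentation, -0.25 for growth factors, -0.23 for glycolysis, -0.16 for oxidative phosphorylation, -0.15 for monocyte markers and -0.0345 for lipid handling. With an estimated correlation 4 of these 11 lists kept the call (DAM, homeostatic genes, cholesterol synthesis and growth factors), and the other 7 lost it, of which fry called antigen presentation, cytokines and glycolysis. Genes near the background outside 5XFAD, such as Mamdc2 and Atp6v0d2, have interactions of approximate size.

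Border macrophage markers were higher in Trem2-/-5XFAD than in 5XFAD by a median of 0.89, and all 16 members had a positive difference; the list was called at the preset correlation and by fry (adjusted p = 7.2e-04) but not with an estimated one (adjusted p = 0.0631). A smaller share of microglia, with every other cell type raised alike, would raise the astrocyte list. Its median was -0.0837 with 3 members called lower, but camera did not call the list (adjusted p = 0.0842). The other types moved apart (medians of -0.21 for neurons, -0.01 for oligodendrocytes, 0.15 for vascular cells, 0.09 for monocytes, 0.16 for lymphocytes and 0.62 for neutrophils). These values were known before the comparison was chosen, and it cannot address a smaller share of microglia with uneven amounts of other cells. The larger number of arrays with Y-linked signal in Trem2-/-5XFAD is argued against by the arrays with that signal alone (4 of 5XFAD and 6 of Trem2-/-5XFAD), where the median was 0.83. Within groups the members varied together from array to array, with a mean pairwise correlation of 0.339, above all 10000 random lists matched on mean level (median -0.00172), so border macrophages passing the sorting gate may have contributed. Microglia that regulate these genes jointly would vary in the same way, which keeps that biological explanation open; it was not tested.

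Of the 30 genes other than Trem2 that changed alike with Trem2 genotype with and without 5XFAD, 6 lie on chromosome 17, as Trem2 does. Of the 200 tested genes nearest to Trem2, 4 were among the 30 (2.00%), against 26 of 12527 elsewhere (0.208%; one-sided Fisher's exact test, p = 0.00118), so DNA of another strain kept beside the targeted allele is a candidate explanation for these. Of these 4, Enpp5, Olfr111, H2-M3 and Mydgf, the Trem2 genotypes did not overlap for Enpp5 alone. Enpp5, Olfr111 and H2-M3 lie close together (positions -68, -77 and -80 from Trem2), while the test takes genes as independent. Olfr111 and H2-M3 also differed with 5XFAD (means of 5.13 and 7.32 in WT, 7.06 and 8.22 in 5XFAD). The other 24 genes lie on other chromosomes, and for 13 of them the Trem2 genotypes did not overlap over 10 and 9 arrays, such as G530011O06Rik and Mid1 on X, Rasgrf2 and Nnt on 13, and Lrmda on 14. Among all 12728 genes 27 showed no overlap, 0.212%, where chance gives 0.00217%. Effects of Trem2 itself, of DNA beside it on distant genes, and of other strain differences stay open and were not tested.

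Salivary gland transcripts stood out in WT 1, WT 2, 5XFAD 1 and 5XFAD 2, where Mucl2, a mucin-like gene, lay between 10.38 and 11.09, against a median of 3.41 and a highest value of 9.65 in the other assigned arrays, and Crisp3 lay between 7.30 and 8.49, against at most 2.59. The Mucl2 value of 9.65 came from Trem2-/- 3, which also had 8.52 for Scgb1b27, and Mucl2 was 7.67 in Trem2-/- 2. Crisp3 and Scgb1b27, like Mucl2, were chosen after their values were seen. A list of 40 further gland genes, some of whose values had been seen, was used to test for RNA of salivary gland. Of its 14 tested genes 1 had its 4 highest values in these arrays, and so had 34 of all 12728 genes (0.267%). That gene was Klk1b16, of the same family as Klk1b22, at 8.07 to 8.96 against at most 3.62 in the other assigned arrays. The rule set for the list asked for more than 1 gene, so the list left gland RNA in these samples possible but undecided. No biological explanation was tested.

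Single arrays lay far from the rest of their group in 16 genes and 6 lists, 22 of 428 groups examined, where chance flags about 1 in 20 groups (21.4). In WT 1 Bhlhe40 was 5.45 (others up to 3.89), Cyp51 6.20 and Cox5b 9.19, and the phagocytic receptor list averaged 8.09. Trem2 was 11.14 in WT 4, and neuron markers averaged 4.83 in WT 2. In Trem2-/- 1 neutrophil markers averaged 7.08 (others up to 5.67). Slc2a1 was 9.09 in Trem2-/- 2, Dkk2 3.89 in Trem2-/- 3, and glycolysis averaged 7.23 in Trem2-/- 4. In 5XFAD 3 Axl was 8.46 and Glb1 8.51, and lymphocyte markers averaged 4.65, while Enpp5 was 5.43 in 5XFAD 2. In Trem2-/-5XFAD 2 Egln3 was 6.42 (others up to 4.87), Clec4a2 7.88, Stab1 8.18 and Cd33 10.37. Gpr165 was 7.79 and H2-Aa 8.996 in Trem2-/-5XFAD 1, Olfr111 was 4.84 in Trem2-/-5XFAD 3, and neuron markers averaged 5.17 in Trem2-/-5XFAD 6.

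Data outside the comparisons were looked at as well. Of 1964 tested probe sets with several genes or none named, limma called 210 higher and 103 lower in 5XFAD than in WT. In the array with conflicting labels, values above all 4 WT arrays were sought among the genes named for Trem2-/- vs WT and Mrc1, and other genes, such as Wdfy1 and Clec10a, lay above them too. The log2 values were 5.86 for Olfr111, 6.89 for Gch1, 5.76 for Cd163, 11.60 for Apoe, 8.05 for Gla, 10.49 for Atf4 and 8.57 for Mrc1. The margin was narrow for Apoe (11.6016 against 11.5992 in WT 1) and Atf4 (10.495 against 10.4665 in WT 2). It was larger for the others. By chance alone a single array lies above 4 others for some genes. The share of all tested genes that did so was not computed, so these values are not shown to exceed chance.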

How the results depend on the processing

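The arrays without the salivary gland transcripts, the neutrophil covariate and the subsets by Y-linked or Xist signal were chosen after seeing the data; the other alternatives were planned. Over all alternatives but single left-out arrays, 2700 of 2845 gene values kept their direction and side of the threshold, 117 lost the call, 26 gained it and 2 changed direction; for lists it was 1045 of 1189, with 139 calls lost and 5 changes of the tested direction. With 1 array left out, 3046 of 3135 gene values and 1119 of 1178 list values kept both, and none of these changed direction. Changes of sign in values that no fit called (11 in all) count as kept. Unless stated, the cause of a moved value was not tested.

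Counts of called genes ranged with 1 array left out from 1639 to 1969 (5XFAD vs WT), 675 to 1025 (Trem2-/-5XFAD vs 5XFAD), 30 to 159 (Trem2-/- vs WT), 158 to 308 (Trem2-/-5XFAD vs Trem2-/-) and 224 to 362 (interaction), and lists from 14 to 15, 13 to 18, 3 to 10, 11 to 14 and 9 to 12. The medians without Trem2, with the genes chosen anew each time, ranged from 0.21 to 0.26 for raised and -0.20 to -0.16 for lowered genes. Counts moved over 1.5 times in Trem2-/- vs WT (159 without WT 2, 42 without WT 3, 30 without Trem2-/- 1, 43 without Trem2-/- 2, 43 without Trem2-/- 3, 46 without Trem2-/- 4; 3 lists without WT 3, 4 without Trem2-/- 1) and in Trem2-/-5XFAD vs Trem2-/- (164 without Trem2-/- 1, 158 without Trem2-/- 3, 185 without Trem2-/-5XFAD 4).

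In 5XFAD vs WT the count was 926 with the covariate of other brain cells, 1100 with a change of at least 1.5 times (by construction fewer), and, with fewer arrays, 856 for Y-linked and 444 for Xist signal. In Trem2-/-5XFAD vs 5XFAD it was 459 with that covariate, 475 with the minimum change and 579 without the 4 arrays, a choice that kept Trem2-/- 3. In Trem2-/- vs WT it was 26 with the conflicting array in WT, 48 with array weights, 11 with only the groups compared, 24 with other brain cells, 21 with neutrophils, 271 without the 4 arrays, 45 for Y-linked and 10 for Xist signal. In Trem2-/-5XFAD vs Trem2-/- it was 507 with array weights, 86 with other brain cells, 159 with the Y-linked covariate and 123 for Y-linked signal. The interaction gave 61 for Y-linked signal. WT and Trem2-/- have 1 array each with Y-linked signal and 5XFAD has 1 with Xist signal, and a lone array is assumed to vary like the others. The covariate of other brain cells did not overlap between WT and 5XFAD, so it also takes out part of that genotype difference.

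Camera with an estimated correlation called 9, 6, 0, 6 and 4 lists, in the order above, against 15, 16, 7, 13 and 11, and fry called 20, 18, 1, 11 and 8 (in Trem2-/- vs WT none of the 7). In Trem2-/- vs WT 3 were called with the conflicting array in WT, 3 with only the groups compared, 4 with other brain cells and 3 with neutrophils; the interaction gave 5 for Y-linked signal. Among arrays with Y-linked signal, Cd163 in Trem2-/- vs WT was -0.13, Lyve1 in Trem2-/-5XFAD vs Trem2-/- 0.22, the medians of the integrated stress response and border macrophage lists in Trem2-/- vs WT 0.0367 and -0.34, and those of cytokines and oxidative phosphorylation in the interaction 0.0689 and 0.0542. The neutrophil list was 0.0728 in Trem2-/- vs WT with its own mean as the covariate, which removes it by construction.

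Each setting chose its own raised and lowered genes, so the medians below are over differing sets. The median of the raised genes without Trem2 was 0.18 with arrays centred, 0.28 with only the groups compared, 0.41 with other brain cells, 0.33 with the Y-linked covariate, 0.19 with a pseudocount of 16, 0.41 for Y-linked signal and 0.34 with the minimum change. The slope of the change without Trem2 on the change with it, another quantity than the median, was 0.335 over all genes. The median of the lowered genes without Trem2 was -0.24 with arrays centred, -0.29 with other brain cells, -0.22 with the Y-linked covariate, -0.14 for Y-linked signal and -0.26 with the minimum change. No scaling moved the median of all genes by over 0.1. Values near the 40th percentile of the arrays (16.9 to 19.2 units) limit the folds of genes such as Gpnmb and Mamdc2, which are low in WT.

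With the replicate number as a block the counts were 1786, 753, 38, 183 and 234. Over 25 same-numbered pairs of arrays the correlation of deviations ran from -0.10 to 0.17, 5 were above 0.1, and 5 of 19 arrays correlated best with their own number, so the numbers were not taken to pair the samples. Between WT and 5XFAD all 4 were positive (0.104, 0.161, 0.0947 and 0.166), arrays 1 and 2 of both groups shared the gland transcripts, and the labels do not say whether a number marks shared handling, which stays open for these groups.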

Other observations

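The tests of border macrophages, of DNA beside Trem2 and of gland RNA are given with the results they concern, and no further hypothesis was tested for the values in this part. Apoe rose by 1.55 ± 0.14 with Trem2 and by 1.36 ± 0.13 without it, with every one of the 11 5XFAD and Trem2-/-5XFAD arrays (12.63 to 13.03) above all 8 arrays without the transgenes (10.88 to 11.74). Apoc1 averaged 4.10 ± 0.16 in WT (SD, n = 4), 6.68 ± 0.69 in 5XFAD (SD, n = 5), 4.30 ± 0.50 in Trem2-/- (SD, n = 4) and 7.98 ± 0.70 in Trem2-/-5XFAD (SD, n = 6), and its interaction (1.09 ± 0.48, limma adjusted p = 0.298) did not pass the test. Cd74 averaged 10.59 ± 0.18 in 5XFAD (SD, n = 5) and 8.44 ± 0.34 in Trem2-/-5XFAD (SD, n = 6), with 8.81 ± 0.40 in WT (SD, n = 4) and 8.64 ± 0.09 in Trem2-/- (SD, n = 4).

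The array with conflicting labels lay outside the range of the Trem2-/- arrays for Trem2 and the genes listed with it next. These values argue against its Trem2-/- label, and it stayed in no group. Its log2 levels of genes that changed with Trem2 genotype were 11.08 for Trem2, 10.68 for G530011O06Rik, 9.62 for Mid1, 5.06 for Rasgrf2, 8.37 for Glo1 and 5.82 for Nnt, against 6.84 to 7.02, 3.54 to 5.17, 5.78 to 6.78, 7.33 to 8.07, 9.35 to 9.59 and 6.68 to 6.92 in the Trem2-/- arrays. Wdfy1 was 7.15, against 6.13 to 6.44 in WT and 7.03 to 7.32 in Trem2-/-, Enpp5 was 5.15, against 5.70 to 6.44 and 3.83 to 4.54, and Lrmda was 7.43, against 7.51 to 7.71 and 4.44 to 6.02. Over all tested genes its mean correlation was 0.968 with the WT arrays, 0.975 with Trem2-/-, 0.952 with 5XFAD and 0.972 with Trem2-/-5XFAD. With single arrays it ran from 0.961 to 0.976 for WT and from 0.972 to 0.978 for Trem2-/-, so these ranges overlapped. It showed Xist signal (9.44), and its border macrophage markers averaged 6.73, against 5.62 to 6.44 in the WT arrays and 6.08 to 6.96 in the Trem2-/- arrays. The gland transcript Klk1b22 was 2.64 in it.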
